A study of Mus musculus with 9 samples.

How the data were processed

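The series holds 9 RNA sequencing libraries from paclitaxel- and antagonist-treated mice, 3 each from DRG, spinal cord and hind paw skin. Per the labels' protocols, about 500 ng of total RNA per sample went through oligo-dT selection, fragmentation and random priming with a stranded kit that marks the second strand with dUTP, and was sequenced as 50 bp single-end reads. Per the submitters' processing notes, bcl2fastq, TopHat2 and HTSeq were used with the mm9 mouse genome. Their versions, the gene models and the strand setting of the counting are not given in the sources used here. Because the strand setting is not stated, overlapping and antisense genes are uncertain. The authors deposited whole-number counts of reads per gene symbol for each library, with 22609 genes and 5 summary rows for reads not assigned to a gene.

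The summary rows stayed out of library sizes and tests. They held 42.9 to 43.3% of each file's total in DRG, 46.2 to 47.7% in spinal cord and 58.1 to 59.3% in paw. Most of that was alignments to several places, at 32.4 ± 0.454% in DRG, 34.4 ± 1.21% in spinal cord and 47.3 ± 0.359% in paw (SD, n = 3). Levels of gene families with near-identical members, such as keratins, tubulins, globins and class II histocompatibility genes, are uncertain because such reads were not counted to genes. Reads assigned to genes ranged from 15537545 to 23229724 per library, and 3 reads, taken as the floor, equal 0.134 to 0.185 CPM. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

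Samples were grouped by the tissue in their titles. All pairs of libraries of a tissue differed by more than sampling noise, with a chi-square per degree of freedom of 7.30 to 36.7, so none was counted as a repeat deposit. The main fit used the deposited counts of all 9 libraries with tissue as the factor and 6 residual degrees of freedom, in edgeR 4.0.16 under R 4.3.3. Low genes were removed with filterByExpr by tissue, library sizes were scaled by TMM, and glmQLFit (robust) with glmQLFTest gave fold changes and p-values, with Benjamini-Hochberg adjustment over the genes tested. The standard error of a fold change is its size divided by the square root of its F. CPM values use the TMM library sizes. A fold against a tissue with 0 reads is a lower bound computed against 3 reads over the group, and one against 1 to 3 reads has a 95% counting interval.

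A set of 26 gene lists was fixed before the data were examined, and 411 of their 415 entries matched a symbol in the files, 6 through an older symbol. The lists cover the lymphotoxin pathway, cytokines, interferon response, sensory neurons, nerve injury, Schwann and satellite glia, oligodendrocytes, astrocytes, microglia, spinal neurons, keratinocytes, fibroblasts and matrix, skeletal muscle, endothelium, erythroid cells, marrow neutrophils, antigen presentation and Langerhans cells, macrophages, T and B cells, mast cells, adipocytes, meninges and choroid plexus, tubulins, paclitaxel handling, analgesic targets and Hox genes. They were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists, and again with the correlation estimated per list. No list passed with the estimated correlation in any comparison. Enriched genes had an adjusted p under 0.05 and a log2 fold change of at least 1 against both other tissues.

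Genes are named by a rule fixed at the same time. It takes the members of the lymphotoxin list, the 5 largest changes in each direction per comparison among genes with at least 10 CPM in the higher tissue and 10 reads in the lower, up to 4 members per list and comparison (the 2 largest called members in the main direction, the most expressed called the other way and the most expressed not called), the 5 most expressed enriched genes per tissue, and the 5 genes with the widest spread per tissue at 20 CPM or more. Values per library are given for some genes, among them Dcn, Acta1, Ngp, Slc4a1, S100a8, Slc6a5, Sprr1a, Ecel1, Atf3 and Myh4. That choice lies outside the rule and was made after the values were seen. The rule itself takes some of these genes, such as Acta1 and Slc4a1 for their spread. Some genes that the rule takes are not reported here.

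The functions were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed per comparison. For DRG against spinal cord, on 15658 genes, 27.3% of the genes changed 1.5-fold, 71.4% of those changed 2-fold and 97.2% of those changed 4-fold were recovered, with 16 false calls of 148. For paw against DRG, on 15829 genes, the shares were 27.1%, 77.2% and 83.6%, with 11 false calls of 135. For paw against spinal cord, on 15583 genes, they were 27.7%, 74.6% and 88.2%, with 10 false calls of 138. These false shares of 10.8%, 8.1% and 7.2% lie above the nominal 5%. Only the 200 changed genes differed between the compared tissues, whereas 59.56 to 81.58% of tested genes were called in the real comparisons. The simulated false shares and recovery therefore do not give those of the real comparisons. None of 25 unchanged lists passed camera in any of the 3 simulations, and the raised list passed in each. The simulated genes were drawn independently, whereas the real muscle list had an estimated correlation of 0.828. The simulations therefore cannot show how often camera passes lists of correlated genes.

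Alternatives were other normalizations, filters, tests and thresholds, the 2 tissues alone, a sample-number block, other set tests, and leaving out each library in turn. A further 4, chosen after seeing the data, left out pairs of libraries or corrected for transcript length. Transcript lengths and GC shares came from GENCODE M21 on GRCm38, used by symbol only, with no coordinates, and covered 15929 of 16091 tested genes. DESeq2 1.42.0 served as an alternative test.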

Results

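RNA was sequenced from 3 tissues of male C57 mice aged 8 to 12 weeks. The tissues were the dorsal root ganglia (DRG) at L3 to L5, which hold the cell bodies of the sensory neurons, the lumbar spinal cord, and punches of hind paw skin. The mice had received paclitaxel, a microtubule-stabilising chemotherapy drug that can cause painful neuropathy, in 2 injections of 2 mg/kg. They had also received an antagonist of the lymphotoxin-beta receptor, 15 µg at each site, in the paw and into the spinal fluid. Tissue was collected 6 days after the last paclitaxel dose. The labels differ on the days of the antagonist. The sample titles give days 1 and 4. The series text gives a time between the paclitaxel doses and 1 day after them. Each tissue had 3 samples, and all 9 carried the same treatment. Samples given control IgG or no antagonist are not analysed here. Every comparison is therefore between tissues of treated mice, and no effect of paclitaxel or of the antagonist was tested. Reads assigned to genes were between 15537545 and 23229724 per library. At these depths 3 reads corresponded to 0.134 to 0.185 CPM, counts scaled to the library size, and 16091 of 22609 genes had enough reads to be tested. Levels below are mean CPM ± SD over the 3 samples of a tissue. Fold changes are on the log2 scale ± their standard error. A gene is called higher or lower where its Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test was under 0.05. The labels do not say that the samples of a tissue came from separate mice, so the p-values measure the spread between these samples only.

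Transcripts of the receptor that the antagonist blocks were found in all 3 tissues. Ltbr, the lymphotoxin-beta receptor, stood at 31.3 ± 2.71 CPM in DRG, 21.3 ± 1.01 CPM in spinal cord and 45.1 ± 6.94 CPM in paw. It was higher in DRG than in spinal cord by 0.56 ± 0.12 (adjusted p = 0.00213). It was higher in paw than in DRG by 0.53 ± 0.12 (adjusted p = 0.00172) and than in spinal cord by 1.08 ± 0.12 (adjusted p = 5.92e-06). Transcripts of its ligands were near the limit of detection. Ltb, the membrane-bound subunit of the lymphotoxin heterotrimer, had 33 reads over the 3 DRG libraries, 59 over spinal cord, of which 34 were in sample 1, and 20 over paw. Lta, the other subunit, had 13, 17 and 22 reads, and Tnfsf14, the second ligand of the receptor, 25, 19 and 11 reads in DRG, spinal cord and paw. Neither passed the filter for testing. Tnfrsf14, the other receptor of Tnfsf14, stood at 1.63 ± 0.496 CPM in DRG, 0.878 ± 0.48 CPM in spinal cord and 0.703 ± 0.102 CPM in paw. It was called only in paw against DRG (−1.21 ± 0.43).

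**Figure D1:**
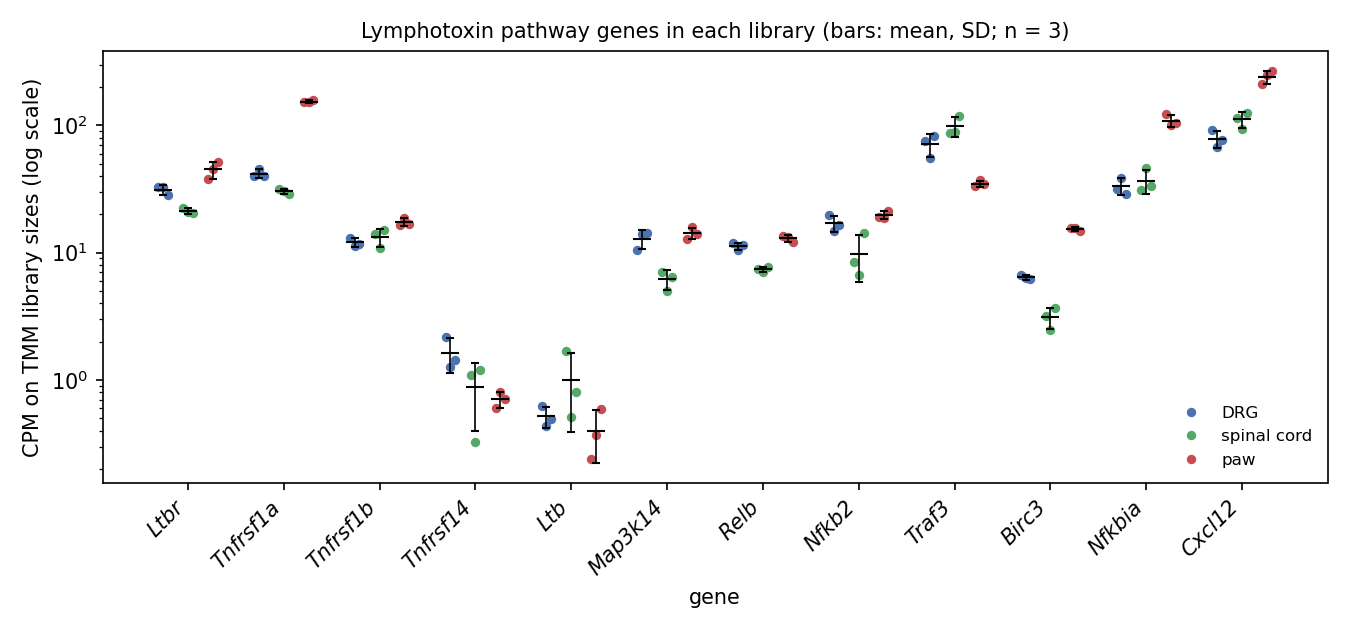
CPM on a log axis of 12 lymphotoxin pathway genes (horizontal axis) in each of the 9 libraries, points coloured by tissue, with black bars for the mean and SD of the 3 samples. Ltbr is seen in every library with paw highest (mean 45.1) and spinal cord lowest (mean 21.3), while Tnfrsf14 lies at or below 2.19 and Ltb at or below 1.70.

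Map3k14, Relb and Nfkb2, of the non-canonical NF-κB pathway that the receptor feeds, were lowest in spinal cord. Map3k14, the NF-κB-inducing kinase, was at 12.9 ± 2.12 CPM in DRG, 6.19 ± 1.09 in spinal cord and 14.2 ± 1.48 in paw. Relb was at 11.3 ± 0.696, 7.40 ± 0.379 and 13.02 ± 0.824 CPM. Nfkb2 was at 16.99 ± 2.57, 9.84 ± 4.01 and 19.8 ± 1.4 CPM. All 3 were called higher in DRG and in paw than in spinal cord, and none of them was called between paw and DRG (adjusted p = 0.437, 0.127 and 0.397). Chuk, another kinase of this pathway, differed in order, with 34.4 ± 1.39 CPM in DRG, 40.1 ± 2.15 in spinal cord and 49.4 ± 0.731 in paw. Traf3, which restrains this pathway, had the order opposite to Map3k14, Relb and Nfkb2, with 71.0 ± 14.1 CPM in DRG, 98.3 ± 17.5 in spinal cord and 34.9 ± 1.88 in paw. Tnfrsf1a, a receptor for tumour necrosis factor and soluble lymphotoxin, was at 154 ± 2.86 CPM in paw and lay above DRG by 1.88 ± 0.09 and above spinal cord by 2.34 ± 0.09. Birc3, an NF-κB target, was higher in paw than in DRG by 1.25 ± 0.15 and than in spinal cord by 2.31 ± 0.16. Nfkbia was higher by 1.71 ± 0.16 and 1.57 ± 0.16, and the chemokine Cxcl12 by 1.62 ± 0.14 and 1.11 ± 0.14. The level of Tnfsf13b was higher in spinal cord, at 4.52 ± 0.815 CPM against 2.05 ± 0.197 in DRG and 2.01 ± 0.226 in paw. Cxcl13 had 3 reads over DRG, 0 over spinal cord and 42 over paw, and Ccl19 and Ccl21a had 0 reads in every library. The haemoglobin symbols Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 also had 0 reads in every library, although the red cell genes Alas2 and Slc4a1 had reads. Reads were also counted to the red cell gene Beta-s, which the fixed erythroid list did not hold. Zeros under these haemoglobin symbols therefore do not show that the counts lack haemoglobin reads. Reads with several alignments were not counted to genes, so zeros of genes with near-identical copies do not show absence.

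Of 18 tested members of the lymphotoxin pathway list, 13 were called between DRG and spinal cord (8 higher and 5 lower in DRG). Between paw and DRG 11 were called (9 higher and 2 lower in paw), and between paw and spinal cord 16 (13 higher and 3 lower in paw). Of all tested genes 59.56% were called between DRG and spinal cord, 80.45% between paw and DRG and 81.58% between paw and spinal cord. Called members alone therefore do not set this list apart. The counts of members adjusted over the list alone were the same. The list as a whole passed the competitive set test (limma camera, preset correlation of 0.01) in paw against spinal cord (adjusted p = 0.0356, but adjusted p = 0.528 with an estimated correlation). Without spinal cord sample 2 adjusted p = 0.0511 resulted. It did not pass in DRG against spinal cord (adjusted p = 0.444) or paw against DRG (adjusted p = 0.0948). Several single calls ended when 1 library was left out. The number of members lower in DRG than in spinal cord then ran from 2 (without DRG 2) to 6 (without spinal cord 2). The number higher ran from 6 (without DRG 1) to 8. Between DRG and spinal cord the call of Nfkb2 was lost without DRG 1 (adjusted p = 0.0539) or spinal cord 2 (adjusted p = 0.0578). That of Traf3 was lost without DRG 2 (adjusted p = 0.0838) or spinal cord 3 (adjusted p = 0.104), and those of Rela, Birc2 and Chuk were lost likewise. The Tnfrsf14 call in paw against DRG was lost without DRG 1 (adjusted p = 0.0977), paw 1 (adjusted p = 0.0725) or paw 3 (adjusted p = 0.0554). Ltb was called lower in paw than in spinal cord (−1.31 ± 0.51). This call was lost without spinal cord 1 (adjusted p = 0.218), paw 1 (adjusted p = 0.108) or paw 2 (adjusted p = 0.0847). With DRG 1 and DRG 2 left out, 6 members were called between DRG and spinal cord in place of 13, and the Ltbr call was lost (0.41, adjusted p = 0.0865). The Ltb call was also lost with DESeq2 (adjusted p = 0.053) and limma-voom (adjusted p = 0.0529).

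The comparison of DRG with spinal cord asked which transcripts set the peripheral ganglia apart from the cord in the treated mice. Genes of sensory neurons were among the highest in DRG and genes of central glia and inhibitory neurons among the highest in spinal cord. The sodium channel Scn10a was higher in DRG by 9.71 ± 0.49, Tmem233 by 9.75 ± 0.34, the transcription factor Prdm12 by 9.57 ± 0.32 and the actin regulator Avil by 9.56 ± 0.30. Among genes with at least 10 CPM in the higher and 10 reads in the lower tissue, highest in spinal cord were Slc32a1, the vesicular transporter for GABA and glycine (−10.16 ± 0.43, adjusted p = 4.06e-08), and the oligodendrocyte gene Ermn (−10.04 ± 0.16). They were followed by Olig1 (−9.90 ± 0.23) and Mobp (−9.84 ± 0.36), also oligodendrocyte genes, and the zinc transporter family gene Slc39a12 (−9.29 ± 0.25). In all 9584 genes were called, 4660 higher and 4924 lower in DRG, and 4577 of them by at least 2-fold, 2261 higher and 2316 lower. Which direction held more 2-fold genes changed without spinal cord 3 (2424 higher and 2388 lower), with DRG 2 also left out (2461 and 2404), and without spinal cord 1 and 3 (2366 and 2314).

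All 30 tested members of the sensory neuron list were called, 28 of them higher in DRG (camera adjusted p = 2.48e-14, adjusted p = 0.052 with an estimated correlation). The itch receptor gene Mrgpra3 had no read in spinal cord and was at least 204-fold higher in DRG, and Mrgprd was higher by 10.33 ± 0.47. The neurotrophin receptor Ntrk2 was lower by 1.16 on the log2 scale at 169 ± 24.5 CPM against 377 ± 10.7 CPM. The Schwann and satellite glia list had 13 members higher and 2 lower of 16 (camera adjusted p = 0.00123, adjusted p = 0.608 with an estimated correlation). The low-affinity neurotrophin receptor Ngfr was higher by 6.34 ± 0.27 and the sodium channel Scn7a by 3.61 ± 0.33. Mbp, a myelin gene that oligodendrocytes also express, was lower (−0.97 ± 0.16). Within spinal cord this list differed between samples, with a median log2 difference of 1.19 between sample 3 and the others. The fibroblast and matrix list had 12 members higher and 2 lower of 16 (camera adjusted p = 0.00522, adjusted p = 0.711 with an estimated correlation), led by Postn (4.23 ± 0.22) and Lum (2.97 ± 0.43). Of its 16 members 14 were highest in spinal cord sample 3 among the spinal cord samples, with Dcn at 160, 137 and 470 CPM in samples 1 to 3. The interferon response list had 12 of 14 members higher and none lower (camera adjusted p = 0.00111, adjusted p = 0.518 with an estimated correlation), among them Oasl2 (2.14 ± 0.18) and Ifit1 (1.73 ± 0.21). The antigen presentation list had 9 higher and 1 lower of 12 (camera adjusted p = 0.00963, adjusted p = 0.451 with an estimated correlation), with H2-DMb1 up by 2.20 ± 0.41 and H2-Ab1 by 1.80 ± 0.20. In spinal cord sample 3 the antigen presentation list lay above the other samples by a median of 0.9 and the interferon list by 0.43. The mast cell list had 7 higher and 1 lower of 8 (camera adjusted p = 0.00123, adjusted p = 0.297 with an estimated correlation). The tryptase gene Tpsb2 was at 3.30 ± 0.368 CPM in DRG and 1 read in all of spinal cord, a ratio of 194 with a 95% counting interval of 34.5 to 7710. The tubulin list, which holds the protein family that paclitaxel binds, had 9 higher and 3 lower of 14 (camera adjusted p = 0.0268, adjusted p = 0.696 with an estimated correlation). Neuronal Tubb3 was higher by 2.23 ± 0.17 and Tubb6 by 1.94 ± 0.20, and Tubb4 was lower (−0.87 ± 0.23). That list call ended without DRG 2 (adjusted p = 0.0578) and without spinal cord 3 (adjusted p = 0.0529).

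The skeletal muscle list had 14 higher and 1 lower of 17 in DRG (camera adjusted p = 0.018, adjusted p = 0.762 with an estimated correlation), led by Myh4 (4.39 ± 1.48) and Atp2a1 (4.39 ± 1.22), with Pygm lower (−2.52 ± 0.64). Muscle transcripts differed widely between DRG samples, with Acta1 at 132, 227 and 8.42 CPM in samples 1 to 3. The list call ended without DRG 2 (adjusted p = 0.0804) and without spinal cord 3 (adjusted p = 0.0529). The Myh4 call was lost without any of DRG 1, DRG 2, spinal cord 2 or spinal cord 3 (adjusted p = 0.0738, 0.0724, 0.0841 and 0.107), and the Atp2a1 call without spinal cord 3 (adjusted p = 0.0627). With limma-voom neither was called (adjusted p = 0.118 and 0.0853). With DRG 1 and DRG 2 left out the list had adjusted p = 0.615, with Atp2a1 at −0.04 and Myh4 at 0.01 on the log2 scale.

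The astrocyte list was lower in DRG with 14 of 14 members (camera adjusted p = 1.9e-10, adjusted p = 0.052 with an estimated correlation). So was the oligodendrocyte list with 13 of 14 (camera adjusted p = 2.17e-09, adjusted p = 0.0567 with an estimated correlation). The spinal neuron list had 13 lower and 1 higher of 17 (camera adjusted p = 7.27e-06, adjusted p = 0.0613 with an estimated correlation). The Hox list had 17 lower of 20 (camera adjusted p = 7.27e-06, adjusted p = 0.314 with an estimated correlation). The microglia list had 13 lower and 1 higher of 15 (camera adjusted p = 5.2e-05, adjusted p = 0.333 with an estimated correlation). Examples were the astrocyte filament gene Gfap, at 3.01 ± 0.608 CPM in DRG and 1000 ± 97.7 CPM in spinal cord, and the myelin gene Mog (−10.95 ± 0.26). Others were Gad2, which makes GABA (−8.89 ± 0.22), and the microglial transcription factor Sall1 (−6.94 ± 0.27). The vesicular glutamate transporter Slc17a6 was at 215 ± 24.1 CPM in DRG and 218 ± 2.09 CPM in spinal cord (adjusted p = 0.937). Its relative Slc17a8 was higher in DRG by 3.52 ± 0.25.

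The remaining lists did not pass the set test between DRG and spinal cord. Nerve injury genes were split, with 6 members higher and 6 lower of 16 (camera adjusted p = 0.877). The injury transcription factor Atf3 was higher in DRG by 2.81 ± 0.54 and the neuropeptide Gal by 1.78 ± 0.24, and Stmn4 was lower (−3.46 ± 0.19). Atf3 ranged from 13.2 CPM in DRG 2 to 42.6 CPM in DRG 1. The macrophage list had 6 higher and 1 lower of 13 (camera adjusted p = 0.178). The adipocyte list had 7 higher and 2 lower of 10 (adjusted p = 0.0596). The cytokine list had 5 higher and 5 lower of 14 (adjusted p = 0.544) with Ccl2 higher (2.54 ± 0.41) and Cx3cl1 lower (−5.05 ± 0.11). The endothelial list had 1 higher and 6 lower of 12 (adjusted p = 0.262). The adipocyte list passed the set test with upper quartile factors (adjusted p = 0.0447), without the low-count filter (adjusted p = 0.0427) and without DRG 1 (adjusted p = 0.046), DRG 3 (adjusted p = 0.0285) or spinal cord 1 (adjusted p = 0.0222). The macrophage list passed with DRG 2 and spinal cord 3 left out (adjusted p = 0.0381). With spinal cord 1 and 3 left out the macrophage (adjusted p = 0.0281), T and B cell (adjusted p = 0.0295) and adipocyte (adjusted p = 0.025) lists passed, with 1 spinal cord sample left and its spread taken from the other tissues. The analgesic target list had 7 higher and 8 lower of 17 (adjusted p = 0.544). The paclitaxel handling list had 1 higher and 4 lower of 8 (adjusted p = 0.544) with the efflux pump Abcg2 as the higher member (1.68 ± 0.10). The keratinocyte list had 1 higher and 4 lower of 23 (adjusted p = 0.544). The meninges and choroid list had 3 higher and 3 lower of 10 (adjusted p = 0.61). The T and B cell list had 1 higher of 7 (adjusted p = 0.602). Of the marrow neutrophil list 2 of 12 were lower (adjusted p = 0.438) and of the erythroid list none of 3 was called (adjusted p = 0.602). Both differed between samples, with Ngp at 180, 44.2 and 55.5 CPM and Slc4a1 at 60.5, 4.15 and 6.66 CPM in spinal cord samples 1 to 3. Adjusted over the list alone, the counts changed to 13 higher for the interferon list, 14 higher for the Schwann list, 15 higher for the muscle list and 7 higher for the nerve injury list. They changed to 7 lower for the endothelial list and 0 for the marrow neutrophil list, and were the same for the others. Median, mean and test differed in sign for the nerve injury, T and B cell and analgesic target lists.

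The comparison of paw with DRG set the hind paw skin punches against the ganglia that innervate the paw. The punches also held skeletal muscle transcripts, with Acta1 at 2268, 3540 and 3910 CPM in paw samples 1 to 3. By the same limits on CPM and reads, genes of the stratified epidermis were among the highest in paw and genes of sensory neurons among the lowest. Krtdap, a gene of differentiating keratinocytes, was at 2706 ± 129 CPM in paw and 0.663 ± 0.336 CPM in DRG (11.98 ± 0.32, adjusted p = 2.63e-11). Gm94 had a larger change (12.07 ± 0.32). Next below Krtdap were the epidermal metallothionein Mt4 (11.89 ± 0.26), the cornified envelope gene Lce1a1 (11.76 ± 0.21) and the keratin Krt24 (11.70 ± 0.28). Lowest in paw were Scn10a (−11.55 ± 0.56, adjusted p = 5.18e-08), the neuropeptide gene Calca (−11.07 ± 0.27), the sodium channel Scn11a (−10.90 ± 0.45) and the neurofilaments Nefl (−10.39 ± 0.28) and Nefh (−10.35 ± 0.30). In all 12946 genes were called, 6386 higher and 6560 lower in paw, and 8562 of them by at least 2-fold, 4110 higher and 4452 lower. Which direction held more genes depended on the scaling, with 6882 higher and 6087 lower under upper quartile factors (4473 and 4156 at 2-fold) and 6479 and 6472 under DESeq2 size factors. It also turned with the 2 tissues alone (6417 higher and 6361 lower), without DRG 2 (6398 and 6367), without DRG 2 and spinal cord 3 (6568 and 6565) and without spinal cord 1 and 3 (6691 and 6671).

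All 23 tested keratinocyte genes were higher in paw (camera adjusted p = 4.53e-11, adjusted p = 0.132 with an estimated correlation). Krt2 was the most expressed, at 25470 ± 2720 CPM, and Lgals7 was higher by 11.59 ± 0.22. The keratins are a family of related sequences and reads with several alignments were not counted, so levels of single keratins are uncertain. All 17 muscle genes were higher in paw (camera adjusted p = 0.000986, adjusted p = 0.667 with an estimated correlation), with Myh1 up by 8.29 ± 0.63 and Atp2a1 by 5.25 ± 1.23 over DRG samples that themselves varied. All 13 macrophage genes were higher (camera adjusted p = 0.00177, adjusted p = 0.667 with an estimated correlation), among them Folr2 (4.16 ± 0.29), Ccl8 (3.40 ± 0.32) and F13a1 (2.99 ± 0.30). All 10 adipocyte genes were higher (camera adjusted p = 0.00096, adjusted p = 0.1 with an estimated correlation), with the lipid droplet gene Plin1 up by 5.54 ± 0.27 and the hormone gene Adipoq by 5.13 ± 0.38. Of 12 endothelial genes 9 were higher (camera adjusted p = 0.0179, adjusted p = 0.667 with an estimated correlation), with Pecam1 up by 2.27 ± 0.11 and Vwf not called at 98.96 ± 3.89 against 85.2 ± 20.6 CPM. Of 8 mast cell genes 6 were higher (camera adjusted p = 0.0308, adjusted p = 0.667 with an estimated correlation), including Tpsab1 (4.11 ± 0.40) and the receptor gene Mrgprb2 (3.52 ± 0.37). This list call was lost with a prior count of 0.5 (adjusted p = 0.0594).

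All 30 sensory neuron genes were lower in paw (camera adjusted p = 4.53e-11, adjusted p = 0.1 with an estimated correlation). The irritant channel gene Trpa1 had no read in paw and was at least 707-fold lower than in DRG, where it stood at 42.5 ± 5.35 CPM. Of 16 Schwann and satellite glia genes 15 were lower (camera adjusted p = 0.000412, adjusted p = 0.667 with an estimated correlation). Fabp7 was at −9.76 ± 0.25. Of 17 analgesic target genes 13 were lower and 2 higher (camera adjusted p = 0.00325, adjusted p = 0.1 with an estimated correlation). The serotonin receptor genes Htr3a and Htr1a had no read in paw and were at least 2909-fold and at least 184-fold lower, and the cyclooxygenase gene Ptgs1 was higher in paw (4.61 ± 0.11). Of 14 interferon response genes 12 were lower (camera adjusted p = 0.0112, adjusted p = 0.667 with an estimated correlation), with Oasl2 at 2.81 ± 0.566 CPM in paw against 48.3 ± 4.5 CPM in DRG (−4.10 ± 0.21) and Irf7 not called. Of 12 marrow neutrophil genes 10 were lower (camera adjusted p = 0.0204, adjusted p = 0.667 with an estimated correlation), with Ngp at −8.27 ± 1.19 over DRG levels of 42.4, 98.6 and 31.8 CPM in samples 1 to 3.

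The other lists did not pass the set test between paw and DRG. The tubulin list had 4 higher and 9 lower of 14 (camera adjusted p = 0.124), with Tubb4 (−7.17 ± 0.31) and Tubb3 (−6.15 ± 0.20) lower and Tuba4a higher (0.66 ± 0.14). The nerve injury list had 2 higher and 10 lower of 16 (adjusted p = 0.124), with Gap43, a growth cone gene, lower (−6.99 ± 0.15). The fibroblast list had 8 higher and 2 lower of 16 (adjusted p = 0.063), with Dpt higher (6.22 ± 0.17) and Sparc lower (−1.73 ± 0.16). The microglia list had 10 higher and 3 lower of 15 (adjusted p = 0.063). Both passed without DRG 1 (adjusted p = 0.0329 for the fibroblast and 0.0365 for the microglia list) and without the low-count filter (adjusted p = 0.0492 for each). Both also passed with DRG 1 and DRG 2 left out (adjusted p = 0.0414 and 0.0334), and the fibroblast list with spinal cord 1 and 3 left out (adjusted p = 0.0387). The cytokine list had 6 higher and 4 lower of 14 (adjusted p = 0.367), with Il18 higher (4.98 ± 0.12) and Il1a, which had no read in DRG, at least 442-fold higher. The antigen presentation list had 7 higher and 3 lower of 12 (adjusted p = 0.189), with Epcam at 60.1 CPM in paw and 0.109 CPM in DRG and Flt3 lower (−5.31 ± 0.19). The paclitaxel handling list had 4 higher and 3 lower of 8 (adjusted p = 0.762), with the transporter Abcc1 higher (2.65 ± 0.17). The Hox list had 7 higher and 11 lower of 20 (adjusted p = 0.762). The astrocyte list had 4 higher and 7 lower of 14 (adjusted p = 0.762). The oligodendrocyte list had 3 higher and 6 lower of 14 (adjusted p = 0.367). The spinal neuron list had 2 higher and 8 lower of 17 (adjusted p = 0.208). The meninges and choroid list had 1 higher and 5 lower of 10 (adjusted p = 0.208). The T and B cell list had 2 higher and 2 lower of 7 (adjusted p = 0.959). The erythroid list had 0 higher and 1 lower of 3 (adjusted p = 0.367). Adjusted over the list alone, the marrow neutrophil count was 11, the erythroid count 0, the T and B cell counts 2 and 1 and the spinal neuron counts 1 and 8, with no change in the others. Median, mean and test differed in sign for the astrocyte, T and B cell and Hox lists.

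The comparison of paw with spinal cord, by the same limits, had Mt4 and Krtdap again among the 5 largest changes towards paw, and neural genes among the largest towards spinal cord. Highest in paw were Spink5, an epidermal protease inhibitor (12.51 ± 0.44, adjusted p = 8.18e-10), Mt4 (12.19 ± 0.27), Krtdap (12.13 ± 0.32), Fam25c (11.89 ± 0.29) and 2310050C09Rik (11.85 ± 0.27). Lowest were Bcan, a proteoglycan of the brain matrix (−10.63 ± 0.33, adjusted p = 1.45e-10), Ermn (−10.18 ± 0.17), 6330527O06Rik (−10.07 ± 0.32), and the neuronal signalling genes Rit2 (−9.94 ± 0.22) and Rasgrf1 (−9.88 ± 0.21). In all 13127 genes were called, 6422 higher and 6705 lower in paw, and 8747 of them by at least 2-fold, 4215 higher and 4532 lower. The larger direction turned under upper quartile factors, with 6713 higher and 6383 lower (4415 and 4335 at 2-fold), and, for all called genes, without spinal cord 3 (6638 and 6563).

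The keratinocyte list was higher in paw with 23 of 23 members (camera adjusted p = 1.44e-10, adjusted p = 0.115 with an estimated correlation). So were the muscle list with 17 of 17 (camera adjusted p = 0.00018, adjusted p = 0.528 with an estimated correlation) and the adipocyte list with 10 of 10 (camera adjusted p = 0.000347, adjusted p = 0.103 with an estimated correlation). The macrophage list had 12 higher of 13 (camera adjusted p = 0.00107, adjusted p = 0.485 with an estimated correlation). The fibroblast list had 14 higher and 1 lower of 16 (camera adjusted p = 0.00106, adjusted p = 0.528 with an estimated correlation). The mast cell list had 7 higher and 1 lower of 8 (camera adjusted p = 0.00391, adjusted p = 0.288 with an estimated correlation). The antigen presentation list had 9 higher and 1 lower of 12 (camera adjusted p = 0.0116, adjusted p = 0.485 with an estimated correlation). Krt14, a keratin of basal keratinocytes, was at 2691 ± 140 CPM in paw and 0.918 ± 0.522 CPM in spinal cord. The adipokine Cfd was higher by 10.36 ± 0.43, the matrix gene Postn by 7.16 ± 0.24 and Retnla by 5.58 ± 0.51. Cd207, the langerin gene of Langerhans cells, had no read in spinal cord and was at least 241-fold higher in paw at 12.3 ± 2.23 CPM, while Flt3 was lower (−5.72 ± 0.19).

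The oligodendrocyte list was lower in paw with 14 of 14 members (camera adjusted p = 3.04e-06, adjusted p = 0.103 with an estimated correlation). The spinal neuron list had 15 lower of 17 (camera adjusted p = 3.85e-05, adjusted p = 0.103 with an estimated correlation). The astrocyte list had 12 lower of 14 (camera adjusted p = 0.00018, adjusted p = 0.13 with an estimated correlation). The marrow neutrophil list had 11 lower of 12 (camera adjusted p = 0.00976, adjusted p = 0.631 with an estimated correlation). The analgesic target list had 13 lower and 3 higher of 17 (camera adjusted p = 0.00391, adjusted p = 0.103 with an estimated correlation). The Hox list had 14 lower and 3 higher of 20 (camera adjusted p = 0.0116, adjusted p = 0.528 with an estimated correlation). The sensory neuron list had 16 lower and 2 higher of 30 (camera adjusted p = 0.0176, adjusted p = 0.506 with an estimated correlation). The GABA-synthesising enzyme gene Gad1 was lower by 9.81 on the log2 scale at 0.256 ± 0.339 CPM against 239 ± 10.6 CPM, Slc6a11 was at −9.66 ± 0.50, and Hoxb8 at −7.55 ± 0.30. The gap junction gene Gja1, listed with astrocytes, was at 514 ± 90.6 CPM in paw and 523 ± 32.7 CPM in spinal cord (adjusted p = 0.858). The transcription factor Runx1 was 1 of the 2 sensory list members called higher in paw (3.67 ± 0.19). The sensory neuron list call was lost with DRG 2 and spinal cord 3 left out (adjusted p = 0.0591). Within the marrow list Ngp reached 180 CPM in spinal cord sample 1.

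Among the lists that did not pass between paw and spinal cord, the nerve injury list had 6 higher and 10 lower of 16 (camera adjusted p = 0.201), with Ecel1 lower (−6.88 ± 0.93) and Cacna2d1 higher (1.05 ± 0.15). The Schwann list had 8 lower of 16 (adjusted p = 0.195). Its spinal cord samples differed, with the median of 1.19 in sample 3. The endothelial list had 8 higher and 1 lower of 12 (adjusted p = 0.0734), and passed without spinal cord 3 (adjusted p = 0.0438) or paw 1 (adjusted p = 0.0492), and with DRG 2 and spinal cord 3 left out (adjusted p = 0.0419). The cytokine list had 7 higher and 4 lower of 14 (adjusted p = 0.53), with Tlr4 higher (4.23 ± 0.25) and Cx3cl1 lower (−3.57 ± 0.10). The tubulin list had 3 higher and 8 lower of 14 (adjusted p = 0.307), with Tuba8 higher (4.02 ± 0.12). The paclitaxel handling list had 4 higher and 3 lower of 8 (adjusted p = 0.595), with Abcc1 higher (2.90 ± 0.18) and the uptake transporter Slco1a4 lower (−6.06 ± 0.13). The interferon list had 0 higher and 7 lower of 14 (adjusted p = 0.311). The microglia list had 3 higher and 8 lower of 15 (adjusted p = 0.304). The meninges and choroid list had 3 higher and 6 lower of 10 (adjusted p = 0.388). The T and B cell list had 3 higher and 3 lower of 7 (adjusted p = 0.773). The erythroid list had 0 higher and 3 lower of 3 (adjusted p = 0.3). Adjusted over the list alone, the sensory neuron counts were 2 and 15 and the others were the same. Median, mean and test differed in sign for the T and B cell and paclitaxel handling lists.

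Counting the genes at least 2-fold higher than in both other tissues, paw had 3238 enriched genes, spinal cord 1563 and DRG 1127. The most abundant in paw were the keratins Krt2, Krt10 (20640 ± 4540 CPM) and Krt1 (11290 ± 4330 CPM), with Hrnr (7825 ± 1100 CPM) and Calm4 (6204 ± 591 CPM). Among the most abundant in spinal cord were Sparcl1 (5211 ± 226 CPM) and the synaptic gene Snap25 (3685 ± 486 CPM). Among those in DRG were the peripheral myelin gene Pmp22 (6336 ± 1010 CPM), the neurofilaments Nefl (4778 ± 407 CPM) and Nefm (4452 ± 394 CPM), and Mtap1b (4419 ± 439 CPM). By list, 28 of 30 sensory neuron genes, 11 of 16 Schwann genes and 6 of 14 interferon response genes were enriched in DRG. In spinal cord they were 12 of 14 oligodendrocyte, 11 of 14 astrocyte and 9 of 20 Hox genes. In paw they were 11 of 13 macrophage, 10 of 10 adipocyte and 17 of 17 skeletal muscle genes, so the paw count is not of skin alone. Each count needs the same libraries in both of its contrasts. Independent lists of the same sizes would share 626 genes for DRG, 652 for spinal cord and 1077 for paw. The 20 simulated sets with no tissue difference gave at most 0, 1 and 0 enriched genes. As no gene differed between tissues in those sets, they cannot show how much shared libraries add to the overlap of contrasts with many called genes. With 3 libraries per tissue the shared tissue could not be split, so part of the excess may come from the shared libraries.

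The samples of a tissue differed by a biological coefficient of variation of 0.141 in DRG, 0.159 in spinal cord and 0.115 in paw. Each value depended on 1 library, and was 0.1002 without DRG 2, 0.0931 without spinal cord 3 and 0.0778 without paw 1. The genes with the widest spread over the DRG samples were all muscle genes, Atp2a1, Myh4, Tnnt3, Acta1 and Ckm. In spinal cord they were the red cell genes Slc4a1, Alas2 and Beta-s, with Rab11fip4 and Syt2, and in paw Defb8, Zmynd17, Myh4, Clec3a and the cartilage gene Chad. Paw sample 1 had 2448 CPM of Myh4 against 443 and 925 CPM in samples 2 and 3. The muscle list as a whole went the other way there, with a median log2 difference of −0.47 in paw 1. Acta1 was at 2268 CPM in paw 1 against 3540 and 3910 CPM in samples 2 and 3.

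**Figure D2:**
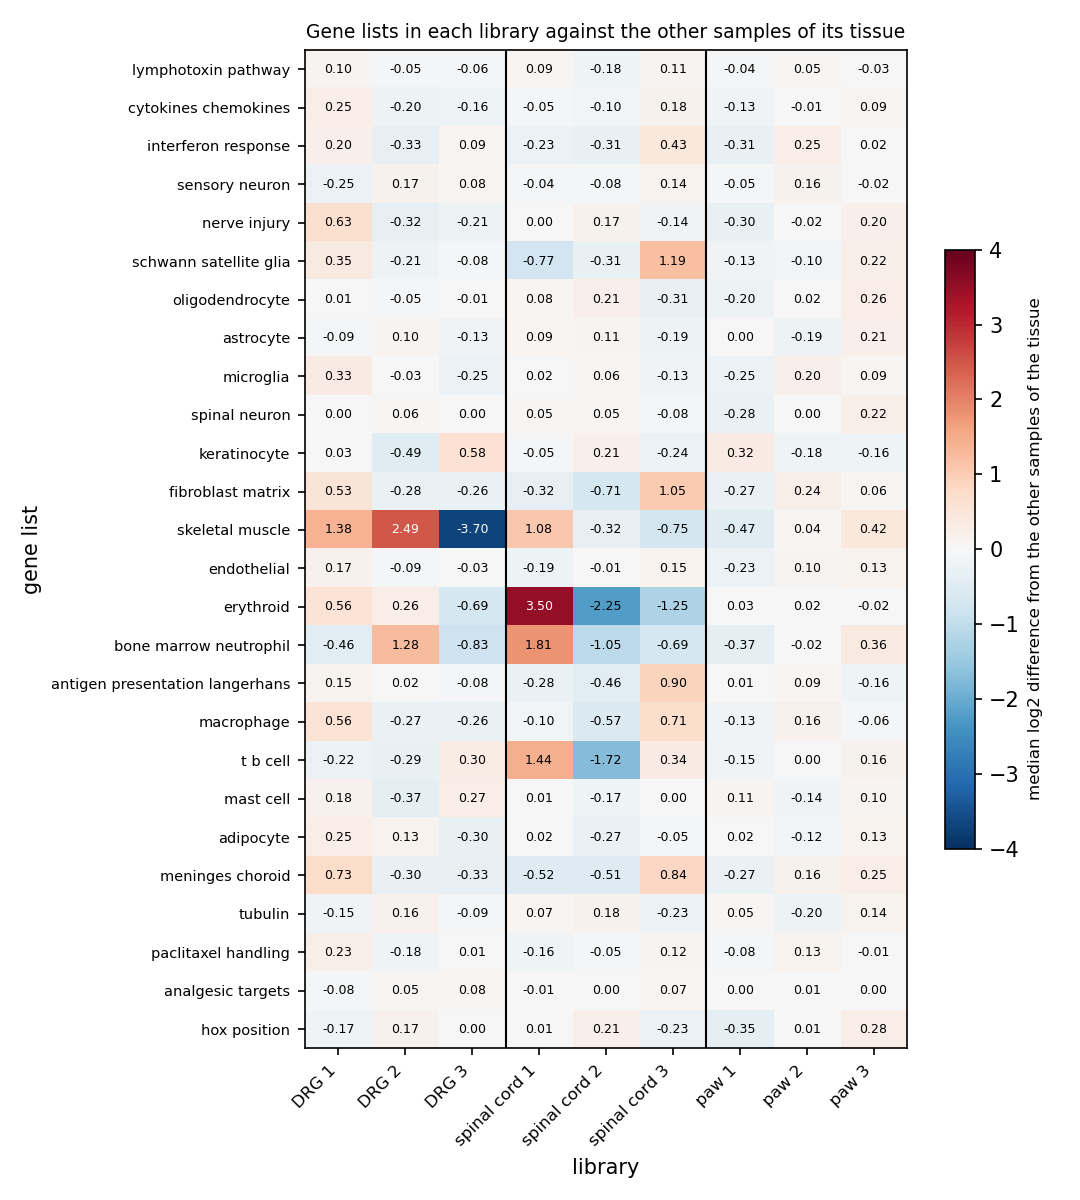
Median log2 difference of each gene list (rows) in each of the 9 libraries (columns) from the mean of the other samples of its tissue, as colour and printed value, with vertical lines between tissues. The largest values are −3.70 for skeletal muscle in DRG 3 and 3.5 for the erythroid list in spinal cord 1, and the Schwann list stands at 1.19 in spinal cord 3.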

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

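Reads that aligned to several places, which no comparison used, made up 32.4% of the file totals in DRG, 34.4% in spinal cord and 47.3% in paw as means of 3 samples. They are listed because they lie outside the gene counts, with no control samples to set them against. They carry no gene name, and what they are was not tested. Groups of 3 samples are too small for a test of single outlying values, and no contrast was shared by 2 groups, so nothing else met the rules for this part.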

How the results depend on the processing

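The counts of called, 2-fold and enriched genes stayed within 1.5 times their value under both other size factors, both other filters, DESeq2, limma-voom, adjusted p under 0.01 and the 4 settings added after seeing the data. So did the called and 2-fold counts with the 2 tissues alone, and the 2-fold counts in the test against a 2-fold minimum. Upper quartile factors moved the median log2 fold change of paw against DRG from −0.02 to 0.10. Enriched genes with a log2 minimum of 2 were 405 in DRG, 770 in spinal cord and 1821 in paw, fewer by the stricter minimum itself. With an estimated correlation 0 lists moved in each comparison, against 13, 11 and 15, with adjusted p from 0.052 to 0.762, 0.1 to 0.667 and 0.103 to 0.631 among those lists. With fry, which does not compare a list with other genes, 24 lists moved in paw against DRG and 24 in paw against spinal cord. With DRG 1 and DRG 2 left out, chosen after seeing the data, 6 lymphotoxin members were called between DRG and spinal cord, and Atp2a1 reversed to −0.0361 (adjusted p = 0.983), with the lone DRG sample assumed to vary like the other tissues, as is the lone spinal cord sample with spinal cord 1 and 3 left out. The cause of these differences was not tested.

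Leaving out each library in turn kept 87.6 to 97% of called genes in the comparisons that hold that library, with no change of sign. For DRG against spinal cord this range was 87.6 to 94.1%. In comparisons without the library left out, up to 99.3% were kept. The coefficient of variation ranged from 0.1002 to 0.165 in DRG, 0.0931 to 0.186 in spinal cord and 0.0778 to 0.147 in paw. Of 6125 values of named genes under an alternative, 5906 stayed called in the same direction or stayed uncalled, 155 lost the call, 63 gained one and 1 reversed. The direction of uncalled genes was not compared. Many of these genes were named for their large changes in the same data, which favours keeping the call. Of 9 correlations of same-numbered deviations 2 exceeded 0.1 (range −0.13 to 0.271), both between DRG and spinal cord (0.271 for sample 2 and 0.217 for sample 3). Correlations of differently numbered samples ran from −0.447 to 0.341. These values therefore do not decide whether equal numbers mark the same mouse. With the sample number as a block 9500, 12906 and 13074 genes were called in DRG against spinal cord, paw against DRG and paw against spinal cord, the list counts stayed at 13, 11 and 15, and 97.2 to 99% of the calls were kept. Depth limits the lymphotoxin ligands, where 3 reads equal up to 0.185 CPM.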

Other observations

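Transcripts of the receptor that the antagonist blocks were present in every tissue, with Ltbr at 21.3 to 45.1 mean CPM. Those of its ligands had 11 to 59 reads per tissue, and protein was not measured. The interferon response list had 6 of 14 genes enriched in DRG and 0 in spinal cord or paw. Marrow neutrophil transcripts such as S100a8 reached 161 CPM in spinal cord 1 and 89.7 CPM in DRG 2, against 37.5 to 55.1 CPM in the other nervous tissue samples. The glycine transporter Slc6a5 was at 1.65, 1.21 and 16.9 CPM in spinal cord samples 1 to 3.

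The tests of the patterns below were chosen after their values were seen, and the counts over other splits of the samples were planned before. Tests of nerve root, meninges and connective tissue were run and set aside, because they used the genes that showed the patterns.

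Spinal cord 3 had higher Schwann cell and fibroblast transcripts than the other spinal cord samples, and its antigen presentation (0.9), meninges and choroid (0.84), macrophage (0.71), interferon (0.43) and T and B cell (0.34) lists were higher too, as median log2 differences. Its erythroid (−1.25), skeletal muscle (−0.75), marrow neutrophil (−0.69) and oligodendrocyte (−0.31) lists were lower. Each value is a difference from the mean of the other spinal cord samples. Spinal cord 1 was highest on the erythroid (3.5), marrow neutrophil (1.81), T and B cell (1.44) and skeletal muscle (1.08) lists, which lowers the values of spinal cord 3 on them. Spinal cord 2 was lower than spinal cord 3 on the erythroid (−2.25), T and B cell (−1.72) and marrow neutrophil (−1.05) lists. In spinal cord 3 the Schwann list lay above the other spinal cord samples by a median of 1.19 on the log2 scale. There 27 of 32 Schwann and fibroblast members were highest. These lists were singled out because they stood apart. Ganglion tissue in the sample is argued against: the Schwann list implies a ganglion share of 20.2%, while the sensory neuron list implies 0.131%, with Avil at 2.41 CPM against 1070 in DRG. Transcript length as the whole cause is argued against, since the median stays at 1.10 after its trend is removed. Meninges, nerve root or a mix of other tissue in the sample may account for it, none of which a test here decides, and no biological explanation was tested.

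DRG 1 had a higher nerve injury list, by a median of 0.63, with 14 of 16 members highest in that sample, a list and sample singled out because they stood apart. Other lists moved in the same sample: skeletal muscle by 1.38, meninges and choroid by 0.73, macrophage and erythroid by 0.56 each, fibroblast by 0.53, Schwann by 0.35, microglia by 0.33, sensory neuron by −0.25 and marrow neutrophil by −0.46. Sprr1a, a regeneration-associated gene, was at 14.0, 0.965 and 3.07 CPM in samples 1 to 3 and Ecel1 at 10.2, 1.11 and 2.38 CPM. Spinal cord tissue in the sample is argued against, since astrocyte and oligodendrocyte genes imply a share of −0.0159% where the injury genes that cord expresses more need 16.6%, and length correction left the median at 0.63. A different mix of cells in that sample and more injured neurons may both be candidate explanations, neither of which a test here decides, and no group of the design tests a biological one.

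DRG 2 and spinal cord 3 deviated from their tissues in opposite directions over the same genes, with a correlation of −0.448 across genes, which are not independent replicates. This was the most extreme pair between tissues. Other pairs went the other way, with 0.341 for DRG 1 and spinal cord 3 and 0.271 for DRG 2 and spinal cord 2. Deviations of the 3 samples of a tissue are tied together, so these pairs are not independent. The deviations of DRG 2 and spinal cord 3 followed transcript length in opposite ways, with Spearman correlations across genes of −0.344 and 0.387. Other libraries had trends of similar size (−0.369 in spinal cord 2 and 0.292 in DRG 3). Genes over 6 kb had a median of −0.203 in DRG 2 and 0.143 in spinal cord 3. Removing the length trend left the correlation at −0.393 and removing a GC trend left −0.439, which argues against either as the whole cause. What else the 2 libraries share was not tested, and no biological explanation was tested.

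The 6 libraries of 2 tissues divide into 10 splits, the real one included, too few for a share under 0.05. The real split called 9584, 12946 and 13127 genes and 4577, 8562 and 8747 at 2-fold in DRG against spinal cord, paw against DRG and paw against spinal cord, and the highest other split called 0 in each, so 1 split of 10 reached the real count each time. For lists moved, the real counts were 13, 11 and 15 and the highest of the others 16, 12 and 16, and 4, 3 and 4 of the 10 splits gave as many. Why other splits moved as many lists was not tested. For enriched genes, 100 of the possible splits of the 9 libraries into 3 groups were drawn, the real one included. Of these, 3 gave as many as DRG (1127), 3 as many as spinal cord (1563) and 1 as many as paw (3238). The highest other split gave 3192, above the DRG and spinal cord counts. Splits that mix tissues put the tissue difference into the spread within groups, so these shares are a weak test of chance.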
